A study of Drosophila melanogaster with 3 samples.

How the data were processed

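Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to wandering larvae, the last larval stage of Drosophila melanogaster before pupariation, that carried a GFP-tagged (green fluorescent protein) Hr78 transgene made from the gene's own genomic region. The series holds 3 libraries, which are 2 anti-GFP ChIP replicates and 1 input DNA library. Whether the replicates came from separate cultures is not given in the sources used here. 1 peak list for the whole series was used, and no value per library, so no spread between replicates could be computed and no replicate could be left out. Read totals per library were not used here, and the sequencing depth is therefore unknown.

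The deposited list gives a sequence name, a start, an end and a score for each peak. The coordinates are in FlyBase release 5, per the file headers, and the submitters' processing notes name BDGP5. The source column of the deposited list names MACS as the peak caller, and the submitters' processing notes name MACS2, BWA, a short-read aligner, and the Illumina software CASAVA in versions 1.7.0.2 and 1.7.0.3, with no role or order for any of them. The definition of the deposited score, the threshold behind the list and whether the authors pooled the replicates before calling peaks are not given in the sources used here. The score was therefore used to rank and describe peaks within this list and, after its scale had been examined as described next, to read a pile-up and to ask which scores go with the genome-wide background. Positions are printed as deposited, counted from 1 with both ends included.

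The scale of the score was examined from its values. A Poisson series, which is −log10 of the probability of more than k counts for whole k at 1 background mean, was compared with all scores for means from 20 to 200 in steps of 0.01, then in steps of 0.0005 around the best mean. A score was called a match when it lay within 0.0105 of a member of the series. This tolerance was set after shares per arm had been computed with 0.0051, the rounding of a score with 2 decimals, and after some frequent scores were seen to lie just outside it; the narrower tolerance is kept as an alternative. The whole number k is uncertain by 1, because the values do not tell whether the tail includes k itself.

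Peak density was computed on 6 sequences (X, 2L, 2R, 3L, 3R and chromosome 4). With no genome of release 5 at hand, the length of each arm was taken as the highest peak end on it. The number of peaks per arm was tested with a 2-sided exact binomial test against the arm's share of this length, with Benjamini-Hochberg adjustment over the 6 arms. Because peaks lie in clusters, the same difference was also tested by 100000 2-sided permutations of 100 kb bins among arms. Intervals of density ratios are 95% bootstrap intervals from 10000 resamples of these bins. Spacing was compared with 1000 random placements of the same peak widths within each arm, without overlap. Differences in median score were tested by 100000 2-sided permutations of bins, with 2000 bootstrap resamples for the intervals. The stretch next to the centromere was taken as the 2 Mb at the high end of X, 2L and 3L and at the low end of 2R and 3R. Shares carry exact Clopper-Pearson intervals. Bootstrap intervals, exact intervals and p-values describe variation along the genome within this 1 list and do not measure variation between animals or libraries. Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

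The tests were checked on simulated data built from the 4701 peaks of the 6 arms. Of 40 sets with random placement the spacing test called 3, and of 20 sets with 30 percent of the peaks moved beside another peak it called 20. The score test called 20 of 20 sets with 3 added to each X score, and 1 of 20 sets with shuffled scores. The 95% interval of the X density ratio held the true value in 40 of 40 sets. The peaks of these sets were placed at random without clusters, so the check does not show how well the interval covers for clustered peaks. With 70 percent of 4851 simulated scores on a Poisson series, 71.7% were matched, since scores off the series also match by chance.

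The tests of density per arm and of spacing were fixed before the data were examined, as were the smaller peak sets, the gene counts and the wider set of sequences used as other settings. The permutation of bins, the merged peaks in the spacing test, the comparisons of score between sequences, the Poisson series and the windows described were chosen after the list had been seen. The planned rule for named items takes the 20 highest-scoring peaks with the gene nearest to each. The gene table at hand is of RefSeq release 6 and coordinates were not carried over between builds, so peaks are named by position and not by gene. For the same reason 8 planned results were not analysed here. They are the location of peaks relative to genes, the distance to transcription start sites, the AGGTCA receptor site, the other sequence motifs, the gene and tissue marker lists, the score by location, the score by motif, and the peaks at the Hr78 gene. From the release 6 table only the number of annotated genes per arm was used, as an alternative expectation. In that setting the peaks of each Het (assembled heterochromatic) sequence were counted with those of its arm. The alternatives were the 2425 and the 1000 highest-scoring peaks, gene counts as the expectation, all sequences, merged peaks, bins or single peaks as the permuted unit, a 1 Mb centromere stretch, each large arm left out and the narrower tolerance. The deposited scores and the deposited start and end positions, which are in base pairs, were used without further normalisation.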

Results

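Hr78 is an orphan nuclear receptor of Drosophila, related to the vertebrate testicular receptors TR2 and TR4. The experiment mapped the chromatin bound by a GFP-tagged Hr78, expressed from a genomic transgene, in whole wandering larvae. Antibody against GFP was used for 2 ChIP libraries, and 1 library was made from input DNA. The values below come from 1 list of 4851 peaks for the whole series. There is no value per replicate behind any of them, and the sequencing depth is unknown.

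Hr78-GFP peaks were mostly short and were spread over every chromosome arm. The 6 arms X, 2L, 2R, 3L, 3R and 4 held 4701 peaks, 96.9% of the list, and the other 150 lay on heterochromatic, unplaced or mitochondrial sequence. Peaks had a median width of 408 bp, with an interquartile range of 278 to 688 bp and extremes of 201 and 5389 bp. Together the peaks on the 6 arms covered 2.66 Mb, or 2.22% of the 119.7 Mb that the arms spanned up to their last peak. The score given by the authors to each peak had a median of 14.36, with an interquartile range of 10.4 to 27.7 and extremes of 5.42 and 371.82. Higher-scoring peaks were wider, with a Spearman rho of 0.74 across peaks, which are not independent replicates.

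The scores fell on a discrete series. For 3790 peaks (78.1%), the score lay within 0.0105 of −log10 of a Poisson upper-tail probability at a single background mean of 66.9 counts. Means more than 2 away from this one matched at most 22.8% of the scores, with a median of 7.15%. Read on this series, matching peaks had a pile-up of 106 to 630 counts, which is 1.58 to 9.42 times the background mean, and the median ratio was 2.06. The share of matching scores differed between sequences. It was 94.7% on X (exact 95% interval 92.7% to 96.2%) and 85.6% on chromosome 4 (77.0% to 91.9%). On 2L, 2R, 3L and 3R together it was 75.9% (74.6% to 77.3%).

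**Figure D1:**
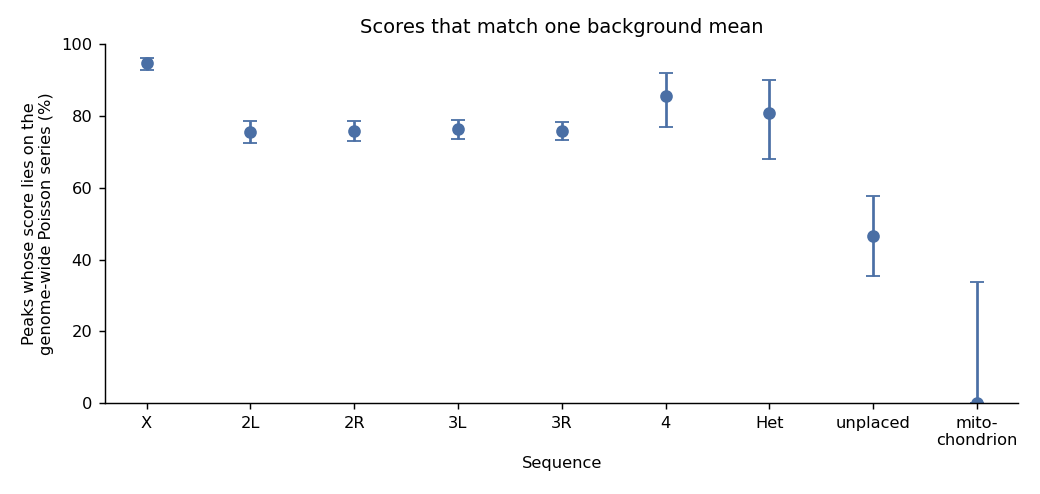
Percentage of peaks, on each sequence, whose score lies on the Poisson series with the genome-wide background mean of 66.9. Points are shares and bars exact 95% intervals, with 94.7% on X, about 76% on each of 2L, 2R, 3L and 3R, and 0 of 9 peaks on the mitochondrial sequence.

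The strongest sites were single positions on several arms, and chromosome 4 held more of them than its length would give. The top score, 371.82, belonged to a 944 bp peak on 3LHet, an assembled heterochromatic sequence of arm 3L, at 1396259 to 1397202, with a pile-up of 9.42 times the background. It was followed by 3R from 8537793 to 8538965 with a score of 329.28 and by 2R from 15993616 to 15994439 with a score of 305.31. On 3R, the peaks at 15686774 to 15687862 and at 11924739 to 11926425 scored 292.41 and 274.35. The widest of the 20 highest-scoring peaks, 2475 bp on chromosome 4 at 199440 to 201914, also scored 274.35, which is 7.86 times the background. The highest X peaks lay at 15689513 to 15690873 and at 19530933 to 19532430, with scores of 253.93 and 245.2. Of the 20 highest-scoring peaks, 5 lay on 3R, 5 on chromosome 4, 3 on X, 3 on 2R, 2 on 3L, 1 on 2L and 1 on 3LHet. The other chromosome 4 peaks in this set lay at 887410 to 888075, at 1081357 to 1082276, at 1346945 to 1348166 and at 1334039 to 1335165, with scores of 240.87, 233.98, 233.97 and 229.95. Chromosome 4 made up 1.13% of the length spanned by the 6 arms.

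**Figure D2:**
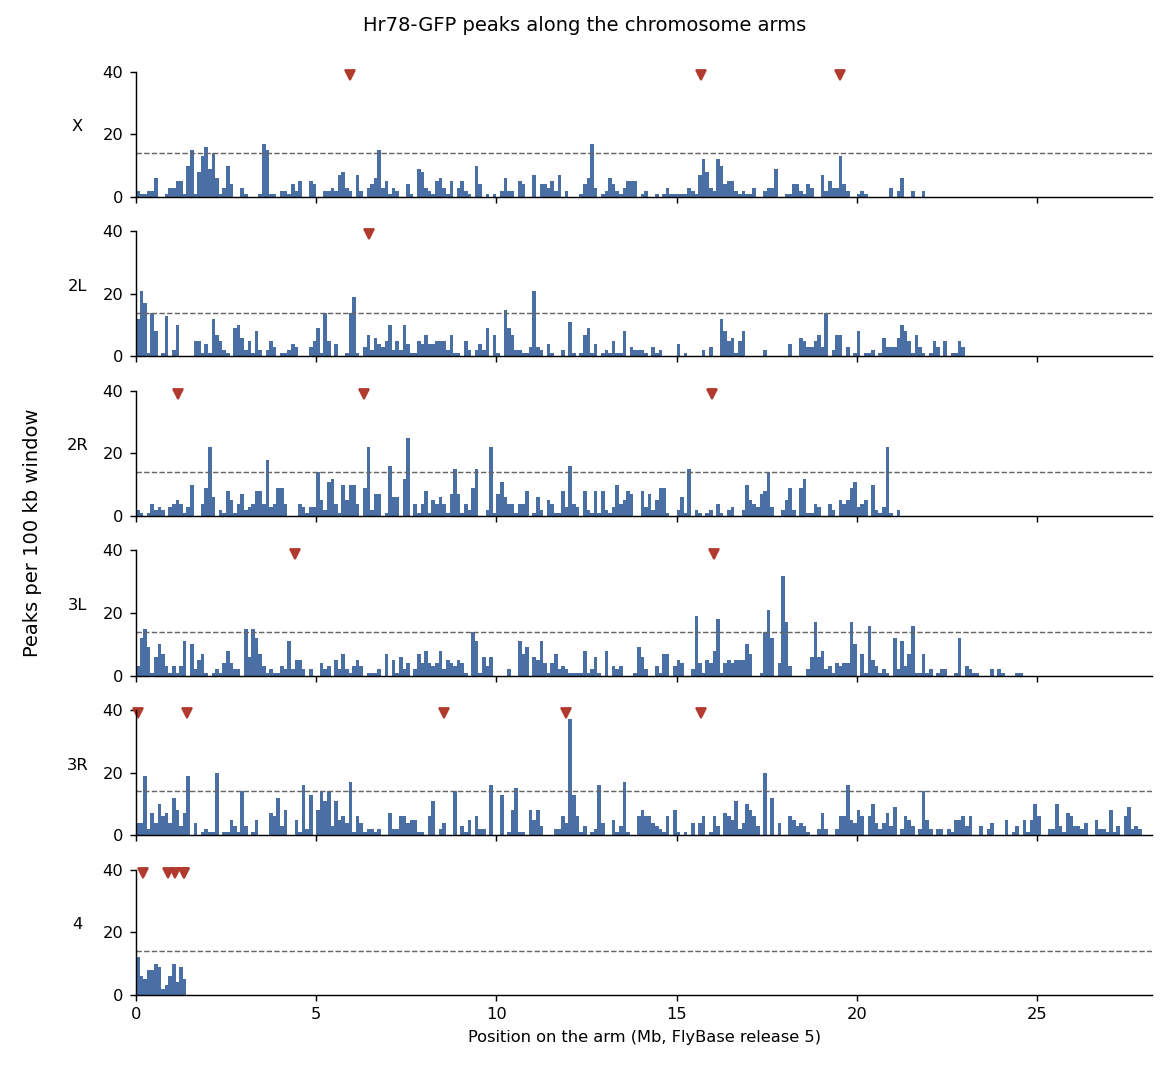
Number of Hr78-GFP peaks in each 100 kb window (bars, vertical axis) along the 6 chromosome arms (horizontal axis in Mb, FlyBase release 5). Triangles mark the 20 highest-scoring peaks apart from the one on 3LHet, and the dashed line at 14 peaks is the 95th percentile of the fullest window under random placement; the fullest window, with 37 peaks, lies on 3R.

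The first planned comparison asked whether Hr78-GFP peaks were distributed over the arms in proportion to length. Peaks were densest on chromosome 4, the small and largely heterochromatic autosome, and sparsest on X. Chromosome 4 carried 97 peaks, or 71.9 per Mb, against 52.9 peaks expected. Its density was 1.85 times that of the other arms (95% interval 1.45 to 2.25). X carried 673 peaks, or 30.8 per Mb, against 858 expected, and its density was 0.75 times that of the autosomes (0.63 to 0.88). Arm 2R carried 980 peaks, or 46.3 per Mb, 1.23 times the density elsewhere (1.05 to 1.43). With gene counts per arm as the expectation and Het peaks counted with their arms, its excess was not past the threshold (log2 0.027, adjusted exact binomial p = 0.519). The other arms had 34.4 (2L), 40.4 (3L) and 42.0 (3R) peaks per Mb. In the exact binomial test the adjusted p was 7.38e-08 for chromosome 4, 4.09e-12 for X, 6.16e-08 for 2R, 4.98e-05 for 2L, 0.0116 for 3R and 0.33 for 3L. When whole 100 kb bins were permuted, the adjusted permutation p was 0.0209 for chromosome 4, 0.0109 for X and 0.0209 for 2R, and 2L (0.0996) and 3R (0.293) were no longer past the threshold.

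The excess on chromosome 4 was larger among strong peaks, and the deficit on X was not seen among them. Of the 1000 highest-scoring peaks, those with a score of 33.59 or more, chromosome 4 held 44, or 32.6 per Mb, 4.43 times the density of the other arms (95% interval 3.27 to 5.65). X held 179 of them, or 8.19 per Mb, 1.09 times the density of the autosomes (0.87 to 1.33). This interval holds both a deficit and an excess. Arm 2R held 179, at 1.13 times the density elsewhere (0.93 to 1.36). Relative to annotated genes, of which the release 6 table lists 2705 on X and 114 on chromosome 4, X had 0.93 times as many peaks per gene as the autosomes (0.78 to 1.09).

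**Figure D3:**
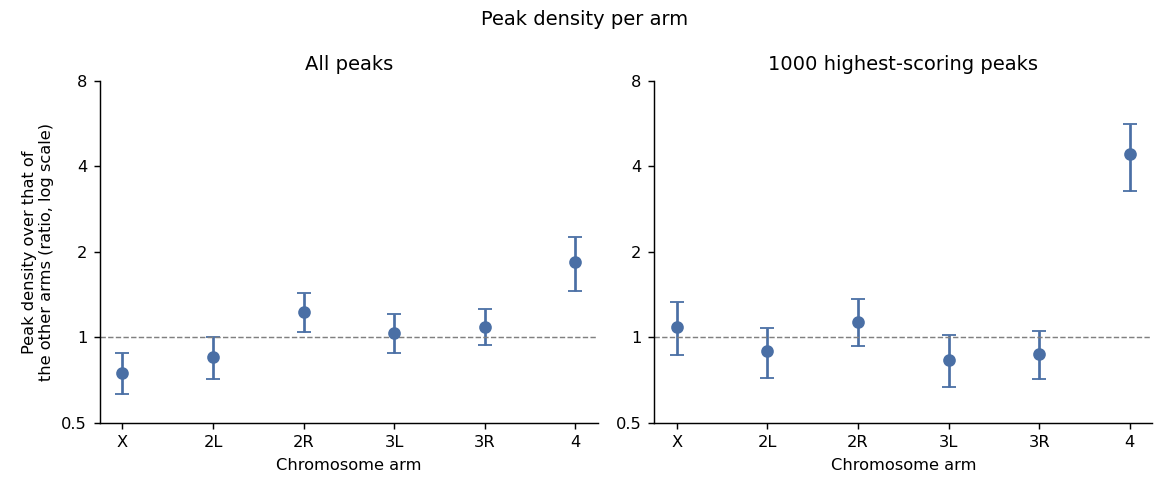
Peak density on each arm divided by the density over the other 5 arms (log scale), for all peaks and for the 1000 highest-scoring peaks. Points are ratios and bars 95% bootstrap intervals over 100 kb bins; chromosome 4 stands at 1.85 and 4.43, and X at 0.75 and 1.09.

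After the list had been seen, scores were compared between arms to see whether sparse and dense arms differed in the strength of their peaks. X peaks scored higher than autosomal peaks, with medians of 17.05 and 13.74. The difference of 3.31 (95% interval 1.52 to 4.40) gave p = 1e-05, the smallest that 100000 permutations of bins can give. Chromosome 4 peaks had a median score of 22.6, against 14.03 for the 5 large arms, a difference of 8.57 (5.35 to 30.07, permutation p = 0.00308). Their upper quartile was 97.8, and 45.4% of them were among the 1000 highest, against 18.9% on the large arms. Peaks on chromosome 4 were also wider, with a median of 546 bp, and those on X had a median of 455 bp, against 391 to 413 bp on the other arms. As given above, X and chromosome 4 also had larger shares of scores on the Poisson series than the other arms.

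**Figure D4:**
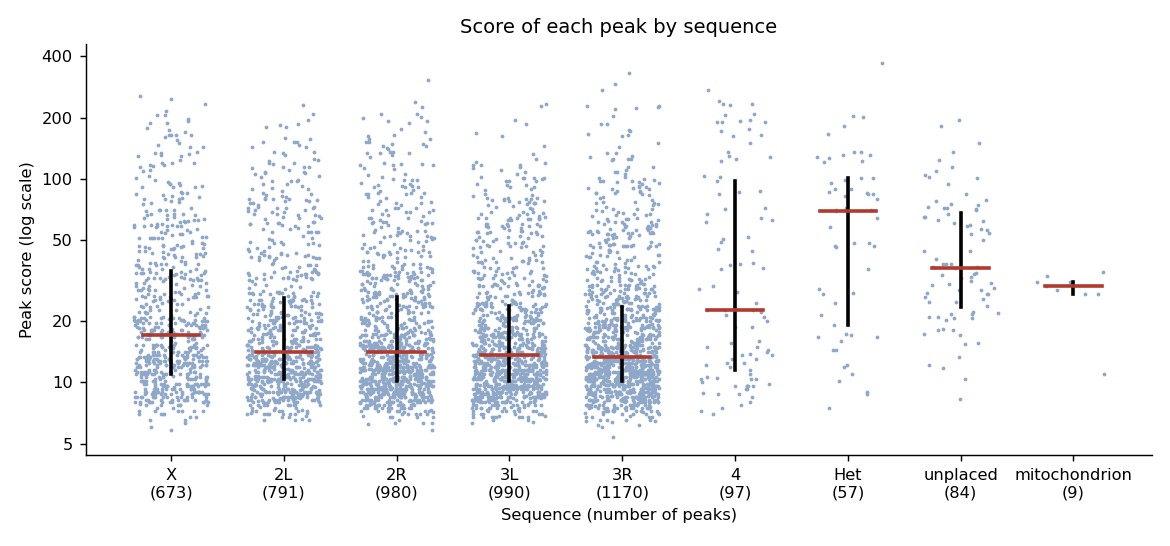
Score of every peak (log scale, 1 point per peak) by sequence, with the number of peaks in parentheses. Red lines are medians and black bars interquartile ranges; medians are 13.4 to 17.05 on the 5 large arms, 22.6 on chromosome 4 and 69.75 on the heterochromatic (Het) sequences.

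Next to the centromeres, peaks were fewer and strong peaks more frequent when the 5 large arms were pooled, but the arms differed. The 2 Mb next to the centromere of the 5 large arms held 295 peaks, at 0.74 times the density of the rest of these arms (95% interval 0.56 to 0.94). For the 1000 highest-scoring peaks the ratio was 1.39 (1.05 to 1.78). The median score was 15.35 there and 14.03 elsewhere, a difference of 1.32 (−0.63 to 5.86) that did not pass the threshold (permutation p = 0.0645). It passed with peaks on the Poisson series alone (4.40, permutation p = 0.00022) and with a stretch of 1 Mb (5.17, p = 0.00032). On 2R the median was 34.4 next to the centromere and 13.7 elsewhere, and on 3L it was 48.2 and 13.7 (adjusted permutation p = 5e-05 for each over the 5 arms). On 3R the medians were 12.8 and 13.4 (adjusted permutation p = 0.491), and X (0.238) and 2L (0.238) did not pass the threshold. Without 3R the pooled difference was 9.76 (permutation p = 1e-05), without X it was 1.52 (p = 0.0263), without 3L it was 0.815 and without 2R it was 0.12, neither past the threshold. Peak density next to the centromere was 9.5 per Mb on X, 29.0 on 2R and 13.5 on 3L, against 32.9, 48.2 and 42.7 on the rest of each arm. On 2L it was 34.0 against 34.5, and on 3R 61.5 against 40.5. Among the 1000 highest-scoring peaks, the ratio of the density next to the centromere to the rest was 1.85 on 2R (95% interval 1.09 to 2.87) and 1.94 on 3R (1.02 to 3.04). It was 1.67 on 2L (0.85 to 2.66), 1.07 on 3L (0.49 to 1.81) and 0.53 on X (0.16 to 1.02), and these intervals hold 1.

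The last planned comparison asked whether peaks lay closer together than random placement would give. They did, and short distances were more frequent than at random. The median distance between neighbouring peak centres was 6122 bp over 4695 pairs, against 17541 ± 259 bp (SD over 1000 placements) at random, a ratio of 0.35. The 2-sided permutation p of 0.002 is the smallest that this number of placements can give. Neighbours within 1000 bp made up 17.6% of pairs, against 1.87% at random. On the 6 arms, peaks separated by at most 500 bp formed 708 groups with 1688 peaks in all. The largest of these groups held 7 peaks over 7480 bp on 3R, from 13525642 to 13533121, with a highest score of 34.04. With such groups merged, 3721 intervals were left on the arms and the ratio of observed to random distance was 0.49. Merging itself removes the short observed distances, so the share within 1000 bp cannot be compared with random placement there. Among the 1000 highest-scoring peaks the ratio was 0.68.

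**Figure D5:**
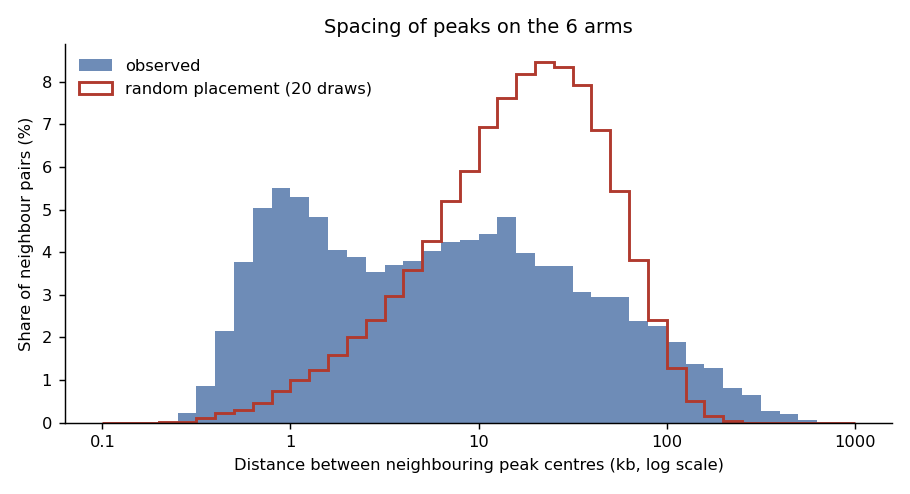
Distribution of distances between neighbouring peak centres on the 6 arms (kb, log scale), as a percentage of neighbour pairs, observed (filled) and for random placement of the same peaks (line, pooled from 20 draws). The observed median is 6122 bp and the random median 17541 bp.

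A small share of windows held more peaks than random placement gave, and long stretches held none. Random placement used every position up to the last peak of an arm, with no allowance for gene density or for sequence to which reads cannot be mapped. Of 1200 windows of 100 kb, 46 (3.83%) held more than 14 peaks, the 95th percentile of the fullest window under random placement, and these 46 windows held 842 peaks, 17.9% of those on the arms. The fullest window was 3R from 12000001 to 12100000 with 37 peaks. It was followed by 3L from 17900001 to 18000000 with 32 peaks and 2R from 7500001 to 7600000 with 25. Dense windows numbered 12 on 3L, 12 on 3R, 11 on 2R, 6 on X, 5 on 2L and 0 on chromosome 4. They were not windows of strong peaks throughout. In the 3R window the median score was 14.03 with 4 peaks among the 1000 highest, and in the 3L window the median was 11.41 with 0. At the other end, 263 windows held no peak, against 26.3 on average at random. There were 26 peak-free stretches longer than 315 kb, the 95th percentile of the longest random gap, and 7 of them lay on 2L and 7 on 3L. The longest were 629 kb on X, from 20295116 to 20924347, and 624 kb on 2L, from 17481632 to 18106115.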

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

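The comparisons in this part were chosen after the peak list had been seen. Besides the 6 arms, 3 kinds of sequence outside the planned comparisons carried peaks. The assembled heterochromatic sequences (Het) held 57 peaks, the unplaced sequences (U and Uextra) 84, and the mitochondrial sequence 9.

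Het peaks were the strongest class of the list. Their median score was 69.75, against 14.03 on the 6 arms (permutation of single peaks, p = 1e-05, the smallest that 100000 permutations can give), and 37 of the 57 (64.9%, exact 95% interval 51.1% to 77.1%) were among the 1000 highest, against 19.5% on the arms (Fisher's exact p = 1.5e-13). By sequence, 2RHet held 20 peaks with a median of 75.1, 3LHet 17 with a median of 84.7, 3RHet 17 with a median of 46.6, 2LHet 2 and XHet 1. On the Poisson series, 80.7% of Het scores matched the genome-wide background (68.1% to 90.0%).

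Unplaced peaks had a median score of 36.6, and 46 of 84 (54.8%, exact 95% interval 43.5% to 65.7%) were among the 1000 highest (Fisher's exact p = 1.5e-12). Their share on the genome-wide Poisson series was 46.4% (35.5% to 57.6%). The p-values and intervals for Het and unplaced peaks treat single peaks as independent and take no account of clusters. Loss of weak peaks and reads shared between repeats were not tested for either class.

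The 9 mitochondrial peaks had a median score of 29.62, with a range of 11.04 to 34.89. The explanation tested was a locally raised background from the high copy number of mitochondrial DNA, under which few scores should lie on the series of the genome-wide mean. The share on that series was 0% (0 of 9, exact 95% interval 0% to 33.6%), against 78.1% for the whole list, which goes with a raised local background. The reading assumes that the caller compares each peak with the larger of a genome-wide and a local background, as MACS is known to do, and the sources used here do not state the settings. Whether the protein was bound there was not tested, nor was any biological explanation.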

How the results depend on the processing

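The permutation of bins, the merged distances, the score comparisons and the narrower tolerance were alternatives chosen after seeing the data. Of 58 alternatives, 35 kept the direction and the side of the threshold or, for values without a test, stayed within the limits set for them (1.5 times for the number of peaks, the quartiles for the width and the exact interval for shares). The spacing ratio stayed under 1 in all 4 of its alternatives (0.49 to 0.68), and chromosome 4 stayed above its expectation, past the threshold, in its 5 (log2 observed over expected 0.87 to 2.09). The higher scores on X and on chromosome 4 kept their calls in all 5 of theirs (2 of which reuse the same difference under another permutation). The arm densities below are log2 of observed over expected. With the 2425 highest-scoring peaks X was at -0.13, no longer past the threshold, 3R turned to -0.017 and 3L turned from 0.040 to -0.029. With the 1000 highest, X turned to 0.098, 3L turned to -0.21, 3R turned to -0.15, and 2L (-0.14) and 2R (0.15) were no longer past it. With genes per arm as the expectation and Het peaks counted with their arms, 2R (0.027) and 3R (0.062) were no longer past it and 3L (0.10) was. With all sequences included, X turned to 0.056, 2L turned to 0.22 and 3L rose to 0.45, but all 6 arms shifted by the same amount, because the added sequences change the common expectation, so the arms kept their values relative to each other. With bins permuted, 2L (-0.19) and 3R (0.096) lost their calls at the same value. Only the test changed there, from a test that treats peaks as independent to a test that moves whole bins. The score difference next to the centromere passed the threshold on series-matching peaks (4.40), with 1 Mb (5.17), without X (1.52) and without 3R (9.76); the cause was not tested. With the narrower tolerance of 0.0051, the share of scores on the Poisson series was 74.8% over all peaks, 91.1% on X and 72.7% on 2L, 2R, 3L and 3R together, lower by construction, and the excess on X was 18.2 percentage points. Alternatives for the 8 results not analysed here were not run, no replicate could be left out of a single list, and the unknown depth limits how far the weak peaks can be read.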

Other observations

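The tests of isolated and neighbouring peaks, the per-gene ratio on X, the score difference on X among series-matching peaks and the density ratios of single arms next to the centromere were chosen after the related values had been seen. Isolated peaks scored higher than clustered ones. The 505 peaks on the arms with no other peak within 20 kb had a median score of 18.11, and the 2368 peaks with another within 2000 bp had a median of 13.08. The difference of 5.03 gave p = 1e-05 (permutation of single peaks, the smallest that 100000 can give), and the median widths were close, at 396 and 399.5 bp. Close peaks lie in groups and are not independent, which this p does not take into account. Among isolated peaks 29.3% were in the 1000 highest, against 13.9% of the close ones.

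Neighbouring peaks had nearly unrelated scores in each of 4 distance classes. For 825 pairs closer than 1000 bp Spearman's rho was -0.02 (adjusted permutation p = 0.554), and for 1360 pairs 1000 to 5000 bp apart it was 0.048 (0.102). It was 0.07 both for 1217 pairs 5000 to 20000 bp apart and for 1293 pairs farther apart, past the threshold in both (adjusted permutation p = 0.0284). These are correlations across pairs of peaks, which are not independent replicates.

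X carried fewer peaks per Mb than the autosomes, and its peaks had a higher median score. Loss of weak peaks on X would also raise its median. It stays open, since the density ratio of the 1000 highest-scoring peaks was 1.09 (0.87 to 1.33). A lower local background within the score itself is argued against as the cause of the higher scores. Among peaks on the series, which share 1 background, the median on X was still 3.00 higher (95% interval 1.28 to 4.58). That comparison cannot decide on a background that acts through the loss of weak peaks, which would raise the median of matching peaks too. For the lower density, a lower background on X stays open. The share of scores on the series was 18.5 percentage points higher on X (16.1 to 20.9), as it would be if the local background there seldom rose above the genome-wide mean and the caller used the larger of both. The share bears on the background, and whether that lowered the number of peaks was not tested. Fewer annotated genes per Mb may also account for the density, since peaks per gene on the arms were 0.93 times those of the autosomes (0.78 to 1.09). The planned binomial test with gene counts as the expectation put X below it, near the threshold (log2 -0.11, adjusted p = 0.0467). Chromosome 4 (1.66), 3L (0.10) and 2L (-0.25) were past the threshold in that test too, and 2R (0.027) and 3R (0.062) were not. Gene number alone therefore did not account for the density of every arm. That test also counted the Het peaks with their arms and treated peaks as independent, so it is not a like comparison with the ratio. A lower copy number of X in larvae of both sexes is left undecided by the density ratio of the 1000 highest-scoring peaks, 1.09 (0.87 to 1.33), and the labels do not give the sex. It would also lower the background on X, so the higher share on the series does not separate these explanations. A difference in Hr78 binding was not tested.

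Scores were higher on chromosome 4 and next to the centromeres of 2R and 3L, while over the 5 large arms the difference of 1.32 (-0.63 to 5.86) did not pass the threshold and ranged from 0.12 without 2R and 0.815 without 3L to 4.40 on series-matching peaks, 5.17 with 1 Mb and 9.76 without 3R. Loss of weak peaks would raise a median score without making strong peaks denser. It cannot be the whole account where the 1000 highest-scoring peaks were denser, as on chromosome 4 (4.43 times) and next to the centromere of 2R (1.85, 95% interval 1.09 to 2.87). It stays open on 3L (1.07, 0.49 to 1.81). Over the large arms pooled the ratio was 1.39 (1.05 to 1.78). That ratio includes 3R, where strong peaks were denser (1.94, 1.02 to 3.04) but scores were not higher, so it does not decide the question. On X and 2L the score difference did not pass the threshold. Wider peaks are argued against as the whole account on chromosome 4. Within 10 width strata its median log2 score was still 0.78 higher (0.38 to 1.06). Score and width rose together (Spearman rho 0.74), and whether width follows from signal was not tested. Next to the centromeres of the 5 large arms pooled, the difference within strata was 0.35 (0.16 to 0.53). That value includes 3R and was not computed for 2R or 3L alone, so it does not decide the question there. Of the strong peaks on chromosome 4 and next to the centromeres, 84.1% (69.9% to 93.4%) and 82.8% (73.9% to 89.7%) lay on the genome-wide series. For these matching peaks, extra copies that raise the local background are argued against, under the assumption about the caller given above. The share next to the centromeres pools the 5 large arms. Of its 99 strong peaks 29 lay on 2R, 14 on 3L and 25 on 3R, and the share was not computed for 2R or 3L alone. Choice by high score may itself favour matching peaks, so the shares do not speak for weaker peaks. Among series-matching peaks of any score, chromosome 4 was still 8.73 higher (permutation p = 0.00588). Reads shared between repeats and a difference in Hr78 binding were not tested.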
